A study of Caenorhabditis elegans with 2 samples.

How the data were processed

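SNPC-4 tagged with GFP was recovered with an anti-GFP antibody from sonicated chromatin of whole young adult hermaphrodites of strain YL551 and sequenced, in 2 biological replicates of 1 group. The deposited processed data are lists of genomic regions in narrowPeak form, in builds ce10 and ce11. The thresholded list (2950 summits in 2860 regions in ce11, 2933 summits in 2844 regions in ce10) holds regions that passed an irreproducible discovery rate (IDR) filter. Unthresholded candidate lists hold 30000 summits each for the pooled replicates, replicate 1 and replicate 2. A region with several summits has 1 entry per summit, and candidate regions are counted by entry below. Per the deposited listing, the thresholded list derives from the candidate lists of both replicates and of the pooled reads, and the reads were scored against a control. The aligner, the peak caller with its version, and the IDR threshold are not given in the sources used here, and the control library is not analysed here.

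The signal of each region is the score that the authors' peak caller gave it, on a scale that depends on depth; medians over the ce11 candidate lists were 27.2 in the pooled list, 16.4 in replicate 1 and 17.7 in replicate 2. Signals of the replicates were therefore compared after division by the replicate's median signal at the IDR peaks (72.2 and 80.0). The -log10 q-value of each region, as deposited by the authors, was at its ceiling of 3.90 for all 2950 thresholded summits and was not used for ranking. The other unit is the summit position, given by the authors as an offset from the start of each region, and positions were converted to 1-based coordinates. Read counts are not given in the sources used here, so depth per replicate and the precision it gives could not be stated, and no minimum was applied.

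Genes and genome sequence came from the RefSeq annotation of WBcel235, the same assembly as ce11. The ce10 lists were used for counts, chromosomes and replicate overlap alone. Class, chromosome and gene comparisons used the 6 nuclear chromosomes, with 2926 IDR summits and, as background, the 26053 pooled candidate regions overlapping no IDR peak. A summit was assigned to an RNA gene within 250 bp and to a protein-coding 5' end within 500 bp. RNA gene classes were snRNA, SL RNA, tRNA, 5S rRNA, snoRNA, piRNA, microRNA and other noncoding RNA. For signal, each peak was given to 1 class in that order, then to protein-coding 5' ends, then to the rest of the genome.

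Counts were compared with Fisher's exact test, 2-sided, and signals with a permutation of class labels on the difference of log2 medians (100000 permutations, 20000 in the alternatives). For the 5S rRNA class, with fewer than 10 peaks, an exact rank-sum test took the place of the permutation of medians. Families of tests were adjusted by Benjamini-Hochberg, and a result passed at an adjusted p of 0.05 or less. Shares carry exact binomial intervals, and rho a bootstrap interval from 1000 draws. With 0 bound genes the odds ratio is 0; where it would be infinite, 0.5 was added to each count; with 0 on both sides it is 1. This convention was set after the first values of the alternatives had been seen. The piRNA clusters are runs of 100 kb bins with at least 20 annotated piRNA genes, joined across gaps of up to 300 kb. The sequence CTGTTTCA and all 8-mers were counted on both strands within 100 bp of each summit and in windows centred 500 bp to either side.

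The comparisons, the 18 gene lists and most alternatives were fixed before the data were examined. The lists were ribosomal proteins, histones, major sperm proteins, vitellogenins, collagens, spliceosome and snRNP proteins, RNA polymerase III and its factors, SNAPc and piRNA transcription, the piRNA and small RNA pathway, germline, intestine, body muscle, neurons, hypodermis, glycolysis, the mitochondrial respiratory chain, translation factors and heat shock. No gene of the annotation carried the names of 3 list members (ubl-1, snpc-3.3 and mut-2). The genes to be named were, by a rule fixed in advance, those within 250 bp of the 10 strongest peaks, the 3 genes with the strongest peak in each RNA class, up to 3 members with the strongest peak in each list, the 5 strongest other protein-coding genes with no RNA gene within 500 bp of the peak, and snpc-4 and unc-119. Not every gene under the rule is printed.

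The alternatives were the 1475 IDR peaks with the highest signal, the strongest regions of each replicate alone, the strongest regions of the pooled list, distances of 100 and 1000 bp, any overlap of the whole region, circular shifts of the peaks along their chromosomes (1000 shifts), the ce10 lists, mean in place of median log2 signal, motif windows of 50 and 250 bp to either side, at least 50 piRNA genes per bin, other definitions of replicate overlap, and removal of peaks near tRNA genes or near RNA genes. Added after the data had been seen were the candidate-region background for the gene lists and the use of 1 summit per region. Division of snRNA genes into U families, the tests of an upstream sequence element, tRNA isotypes, tRNA copies and repeats were also devised after the peaks had been examined.

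The procedure was tested on simulated data, 5 times. Without planted effects, 0 of 45 class tests, 0 of 30 chromosome tests and 5 of 90 gene list tests passed after adjustment. The peaks were then drawn at random from candidate regions, while the list tests compare all protein-coding genes. List tests can thus pass without an effect where a list is rich in candidate regions. All 1000 planted tRNA genes were recovered, which was fixed by construction, since each planted summit was set at the 5' end of its gene. The class was called in 5 of 5 simulations. A planted 4-fold signal was recovered as 4.02-fold. In 1 simulation a planted 8-mer ranked first, but 54 of 32894 8-mers passed, its overlapping neighbours among them, so 8-mer counts overstate the number of motifs. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The 24 IDR peaks of the mitochondrial genome were left out of the comparisons.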

Results

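The series measured where SNPC-4 sits along the genome of the nematode Caenorhabditis elegans. SNPC-4 is the Myb-domain subunit of the small nuclear RNA activating protein complex (SNAPc), which acts in the transcription of small nuclear RNA (snRNA) genes and, in the worm, also of spliced leader (SL) RNA and piRNA genes. Whole young adult hermaphrodites of strain YL551, which express SNPC-4 fused to GFP, were collected 60 hours after L1 synchronisation, and chromatin bound by the fusion protein was recovered with an anti-GFP antibody and sequenced (ChIP-seq). There was 1 group of 2 biological replicates, so no test between conditions exists and each comparison sets parts of the genome against one another. An input library was not analysed here, and the deposited lists hold no read counts, so the depth of each replicate is unknown. All coordinates are 1-based and refer to build ce11 (WBcel235).

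The thresholded list held 2950 peak summits in 2860 regions that together covered 1.13 Mb, with a median region width of 456 bp. Of these summits, 2926 lay on the 6 nuclear chromosomes and 24 on the mitochondrial genome, and the class and chromosome comparisons use the nuclear ones. The signal of a peak is the authors' peak score in the pooled replicates; it had a median of 141 and ran from 84.4 to 14797. Peaks passed an irreproducible discovery rate (IDR) filter and are called IDR peaks. The 26053 nuclear candidate regions of the pooled list that overlapped no IDR peak served as background. All IDR summits are among the 2950 strongest regions of that list, so the comparisons set stronger pooled regions against weaker ones. Peaks are not replicates, so p-values over peaks or genes describe this list, and the intervals are exact 95% binomial intervals that cover counting error only.

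Both replicates ranked most IDR peaks among their own strongest regions. Of the 2926 nuclear IDR peaks, 83.3% (95% interval 81.9 to 84.7) overlapped 1 of the 2950 strongest regions of replicate 1, and 87.9% (86.6 to 89.0) overlapped 1 of the 2950 strongest of replicate 2. The signals of the replicates at 2900 peaks matched in both had a Spearman's rho of 0.779 (bootstrap interval 0.761 to 0.797), computed across peaks, which are not independent. Of the background regions, 1.80% and 1.49% overlapped those strongest regions of replicates 1 and 2, and rho was 0.331 over 11969 matched regions. These shares are partly circular, since the list derives from both replicates and from their pooled reads. All 2950 IDR summits are among the 2950 strongest regions of the pooled list, so a single peak need not be strong in both replicates. When an overlap had to span at least 50% of each region, the shares of IDR peaks were 67.7% and 73.4%.

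The strongest peaks lay at genes of small noncoding RNAs. Of the 10 strongest, 5 were at small nucleolar RNA (snoRNA) genes, 3 at SL2 genes, 1 at an snRNA gene and 1 at rpr-1, the gene of the RNA component of RNase P. The strongest peak of all, at II 15025329 to 15026402, had a signal of 14797, and its summit lay 75 bp upstream of the snoRNA gene Y53F4B.47 (WBGene00045141) and 146 bp upstream of the protein-coding gene cmtr-1 on the other strand. Relative to the median IDR peak of each replicate its signal was 97.4 ± 20.7 (SD, n = 2). The next was at V 8500089 to 8500947 in an intron of pxn-1, 37 bp upstream of the snoRNA gene ZK994.7 (WBGene00044958), at 82.6 ± 14.8 times the median IDR peak (SD, n = 2). The peak 47 bp upstream of sls-2.4 (WBGene00004836, I 4171680 to 4172851), which encodes an SL2 RNA, the leader spliced onto downstream genes of operons, reached 69.7 ± 16.3 times the median (SD, n = 2). The peak 24 bp upstream of rpr-1, within an intron of ints-8 on chromosome I, reached 59.7 ± 12.1 times the median (SD, n = 2).

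Structural RNA genes were the classes in which IDR peaks exceeded the background most. A summit lay within 250 bp of an snRNA gene, whose products build the spliceosome, at 85 of 2926 IDR peaks (2.90%) and at 14 of 26053 background regions (0.0537%), an odds ratio of 55.6 (adjusted exact p = 2.04e-69). SL RNA genes had 21 IDR peaks and 0 background regions (odds ratio 386 with 0.5 added to each count, adjusted exact p = 1.72e-21). At tRNA genes the counts were 284 and 170 (9.71% against 0.653%, odds ratio 16.4, adjusted exact p = 2.67e-166), and at snoRNA genes, whose products guide rRNA modification, 107 and 100 (odds ratio 9.85, adjusted p = 4.12e-51). Other noncoding RNA genes (532 and 1372, odds ratio 4.00, adjusted exact p = 1.54e-115) and microRNA genes (19 and 59, odds ratio 2.88, adjusted p = 0.00028) were also above the background. Protein-coding 5' ends, within 500 bp, were at 1262 IDR peaks (43.1%) and 8010 background regions (30.7%), an odds ratio of 1.71 (adjusted exact p = 3.47e-40). Neither piRNA genes (92 and 726, odds ratio 1.13, adjusted exact p = 0.263) nor 5S rRNA genes (2 and 2, odds ratio 8.91, adjusted p = 0.0599) passed. The test was Fisher's exact test, 2-sided, with Benjamini-Hochberg adjustment over the 9 classes. Over the alternative settings the odds ratio of snRNA genes ran from 30.7 to 111 and that of tRNA genes from 8.14 to 18.7. Without peaks near tRNA genes the value of other noncoding RNA genes was 2.43. The piRNA value passed above 1 at a distance of 1000 bp (1.40) and below 1 at 100 bp (0.611), and the ratio of its count to the mean count of circularly shifted peaks was below 1 without passing (0.814). The 5S rRNA value passed at 100 bp (17.8), in the 1475 strongest peaks (19.3) and with the strongest regions of replicate 1 alone (44.1).

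Counted by gene, 65 of 99 snRNA genes (65.7%, 95% interval 55.4 to 74.9), 17 of 30 SL RNA genes (56.7%, 37.4 to 74.5) and 309 of 612 tRNA genes (50.5%, 46.5 to 54.5) had an IDR summit within 250 bp of the 5' end. The share was 28.9% of 346 snoRNA genes (100 genes), 6.96% of 8057 other noncoding RNA genes and 4.52% of 19983 protein-coding genes. Each of these 5 RNA classes exceeded the protein-coding genes, with odds ratios of 40.4, 27.6, 21.5, 8.59 and 1.58 in the order given (largest adjusted exact p = 1.44e-15). Of 15363 piRNA genes, which encode the germline small RNAs bound by PRG-1, 124 had a peak (0.807%), fewer than among protein-coding genes (odds ratio 0.172, adjusted exact p = 3.15e-108). Most piRNA genes lie close together in clusters and are not independent. A protein-coding gene also counted if any of its annotated 5' ends was near a summit. The lower share therefore does not show that SNPC-4 avoids piRNA genes. Counted by peak against the background, their odds ratio was 1.13 and did not pass. For microRNA genes (17 of 260, odds ratio 1.48, adjusted p = 0.150) and 5S rRNA genes (2 of 16, odds ratio 3.02, adjusted p = 0.162) the difference did not pass Fisher's exact test (2-sided, Benjamini-Hochberg over 8 classes). Each replicate's own strongest regions gave 63.6% of snRNA genes in both, 48.5% ± 1.85 of tRNA genes, 29.0% ± 0.204 of snoRNA genes and 4.23% ± 0.379 of protein-coding genes (SD, n = 2), so these classes lay apart by more than the spread between replicates. At 1000 bp the excess of other noncoding RNA genes no longer passed (odds ratio 1.05) and that of microRNA genes did (2.20). Copies of multigene families share reads, so which member of a family holds a peak is uncertain.

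**Figure D1:**
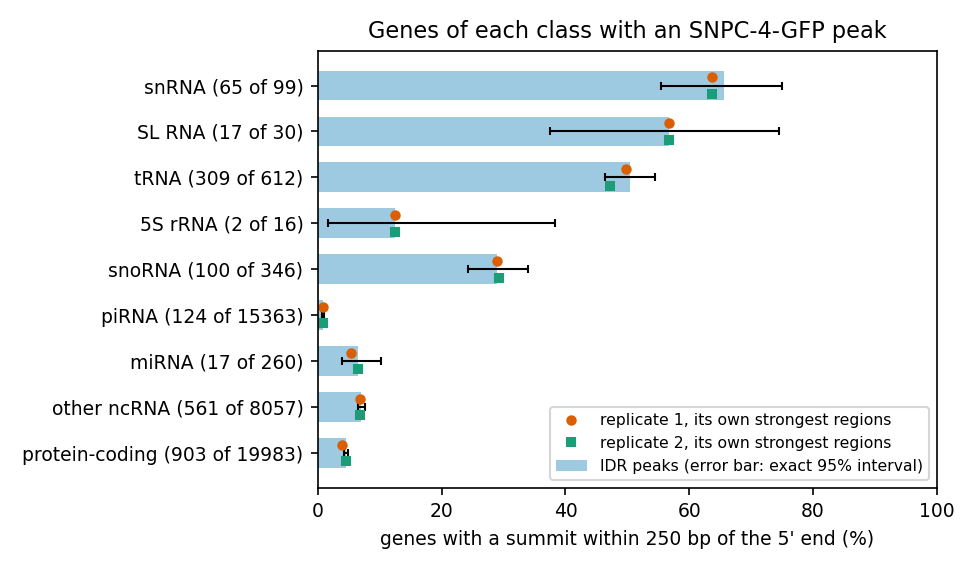
Share of annotated genes of each class (percent, horizontal axis) with an IDR peak summit within 250 bp of the 5' end. Bars show the IDR peaks with exact 95% intervals, and circles and squares show the strongest regions of replicates 1 and 2; snRNA (65.7%), SL RNA (56.7%) and tRNA genes (50.5%) lie far above protein-coding genes (4.52%).

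Among the spliceosomal snRNA families, all 11 U5 genes and all 5 U4 genes had an IDR peak, as did 10 of 12 U1 genes, 15 of 19 U2 genes and 11 of 22 U6 genes. U1 and U2 RNAs recognise the 5' splice site and the branch point, and U4, U5 and U6 complete the spliceosome. Of the 10 genes of SmY RNAs, nematode RNAs of trans-splicing, 9 had a peak, the exception being smy-5. Of the 18 SL2 genes, 17 had a peak, all but sls-2.6, while none of the 12 annotated SL1 genes, which lie in a tandem array on chromosome V, had one. That array held only 3 pooled candidate regions, and gene copies share reads. The missing peaks therefore do not show that SNPC-4 is absent from SL1 genes. A further 20 snRNA genes held none of the family elements and could not be assigned, and 4 of them had a peak. Relative to the median IDR peak of each replicate, the median signal was 16.2 ± 1.90 at bound SL2 genes, 11.1 ± 1.01 at U1, 9.12 ± 0.358 at U6, 7.65 ± 0.0235 at U5, 3.45 ± 0.354 at U4, 3.25 ± 0.124 at U2 and 2.76 ± 0.00906 at SmY genes (SD, n = 2). The strongest snRNA peaks were those of the U6 gene W05B2.8 (III 10989679 to 10989780, signal 9688), the U1 gene sup-6 (II 12944803 to 12944967, 7092) and the U4 gene C52E4.8 (V 11980118 to 11980261, 6101). The annotation does not divide snRNA genes by U number, so U families were assigned from conserved sequence elements after the peaks had been examined, and smy-5, sls-2.6 and the SL1 genes were singled out then too. No test between families was run.

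Signal at IDR peaks was highest at SL RNA genes. Each peak was given to 1 class, and the median signal of 21 SL RNA peaks was 2015, against 129 for 1024 peaks at protein-coding 5' ends, a log2 difference of 3.97. The difference was 2.08 for 85 snRNA peaks, 1.18 for 105 snoRNA peaks and 0.26 for 253 peaks at other noncoding RNA genes (adjusted p = 2.67e-05 for the SL RNA, snRNA and snoRNA classes, from the smallest p the permutations can give, 1e-05, and 0.0001 for the other noncoding RNA genes). In units of each replicate's median IDR peak these classes stood at 15.8 ± 1.42, 5.01 ± 0.108, 2.02 ± 0.0600 and 1.13 ± 0.0170, and protein-coding 5' ends at 0.897 ± 0.0496 (SD, n = 2). Peaks at tRNA genes, the templates of RNA polymerase III with internal promoters, were far more numerous (283) but no stronger by the test, with a log2 difference of 0.10 (adjusted p = 0.109 by permutation) and a relative signal of 0.948 ± 0.00325 (SD, n = 2). Differences at 73 piRNA peaks (0.18), 17 microRNA peaks (0.29) and 2 5S rRNA peaks (0.87) did not pass either (adjusted p = 0.109, 0.133 and 0.109 by 2-sided permutation tests, exact rank-sum for 5S rRNA, Benjamini-Hochberg over 8 classes). With the signal of replicate 1 in place of the pooled signal the tRNA, piRNA and microRNA classes passed (log2 0.14, 0.42 and 0.48), and with that of replicate 2 they did not (0.02, 0.12 and -0.01). The microRNA difference passed with means in place of medians (0.84) and the piRNA difference fell below 0 at 100 bp (-0.06).

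**Figure D2:**
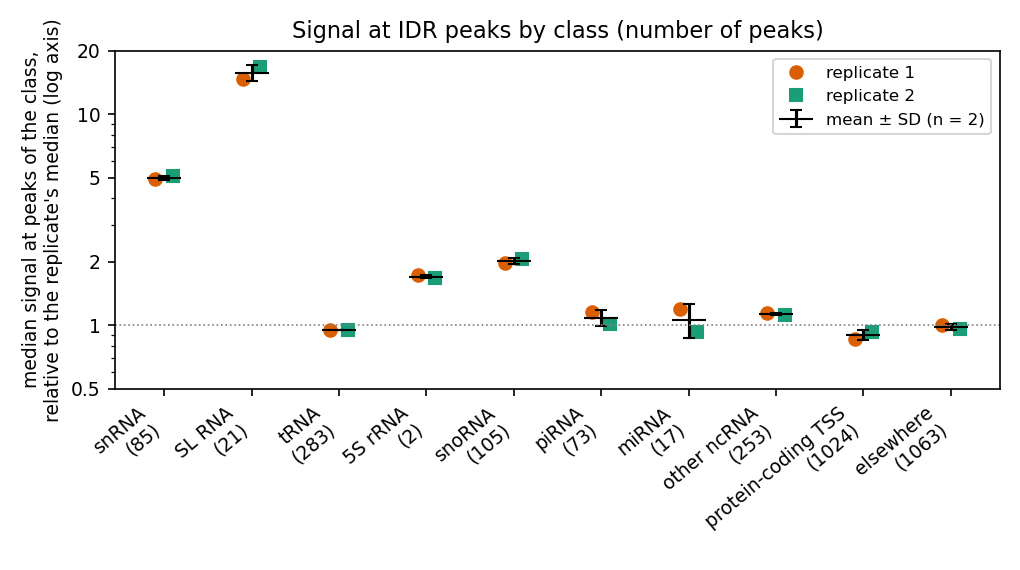
Median signal at the IDR peaks of each class relative to the median IDR peak of the same replicate (log axis), with the number of peaks under each class name. Circles and squares are replicates 1 and 2 and bars show their mean ± SD (n = 2); SL RNA peaks (15.8) and snRNA peaks (5.01) stand above all other classes in both replicates.

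At snRNA, SL RNA and snoRNA genes most summits lay just upstream of the transcribed sequence. The median position was 43 bp upstream of the 5' end at 65 snRNA genes, 47 bp at 17 SL RNA genes, 50 bp at 100 snoRNA genes and 54 bp at 17 microRNA genes, and the summit was upstream at 57, 16, 90 and 13 of these genes. At 309 tRNA genes the median summit lay 8 bp downstream of the 5' end and 43.7% of summits were upstream (95% interval 38.1 to 49.4). At 124 piRNA genes the median summit lay 132.5 bp downstream (29.0% upstream), and at 561 other noncoding RNA genes 61 bp downstream (30.3% upstream). Many summits near other noncoding RNA genes also lie near an RNA gene of another class. Of 532 such peaks, 253 were left to this class when each peak was given to 1 class. At the 1487 protein-coding genes with a summit within 500 bp of a 5' end, the median was 191 bp upstream and 85.8% of summits were upstream. Positions are the authors' summit calls in the pooled replicates, and no test between classes was run.

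**Figure D3:**
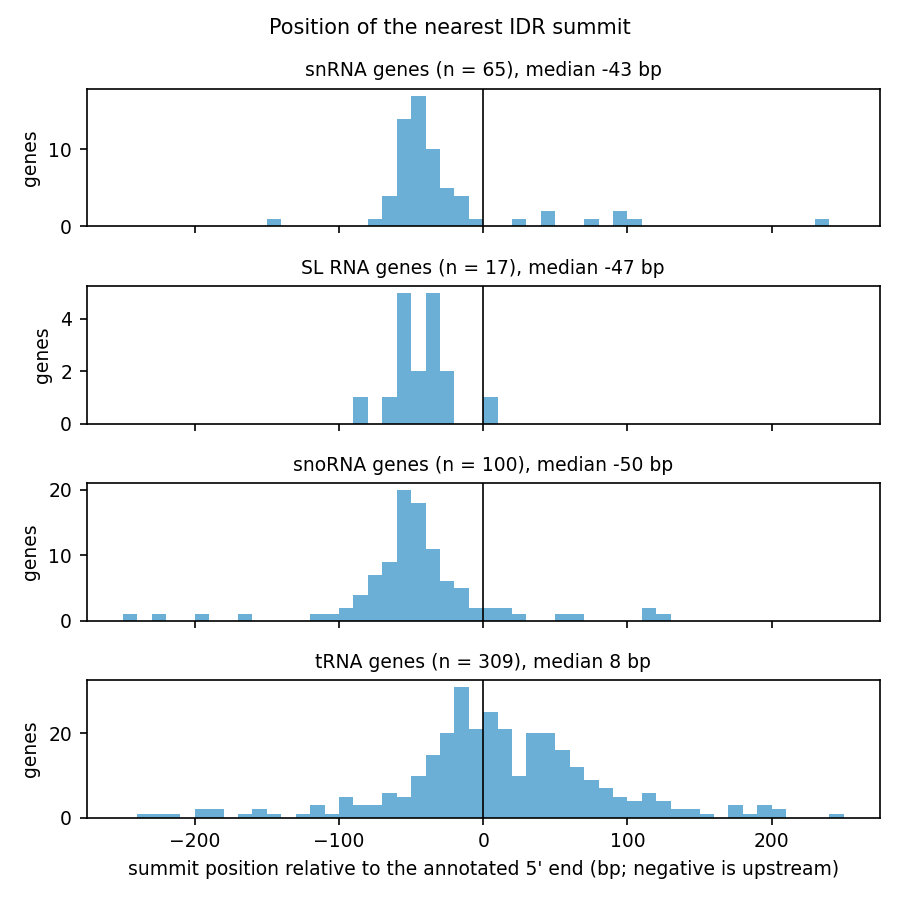
Position of the nearest IDR summit relative to the annotated 5' end (bp, negative values upstream) for bound genes of 4 classes; bars count genes. Median positions are 43, 47 and 50 bp upstream at snRNA, SL RNA and snoRNA genes and 8 bp downstream at tRNA genes, where summits lie on both sides of the 5' end.

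The X chromosome holds 276 of the 612 annotated tRNA genes, and its tRNA genes carried peaks about as often as those of the autosomes. With the gene body as reference, 146 of 276 tRNA genes on X (52.9%, 95% interval 46.8 to 58.9) and 170 of 336 on autosomes (50.6%, 45.1 to 56.1) had an IDR summit within 250 bp, an odds ratio of 1.097 (adjusted exact p = 0.626). For 284 tRNA genes inside introns of protein-coding genes the share was 50.4%, against 52.7% of the other 328 (odds ratio 0.909, adjusted exact p = 0.626). Neither difference passed Fisher's exact test (2-sided, Benjamini-Hochberg over both), and the odds ratio of X was 0.949 at a distance of 100 bp. The strongest tRNA peaks were at C27A2.t1 in an intron on chromosome II (40.6 ± 0.641 times the median IDR peak), M01E5.t1 on I (31.8 ± 6.29) and ZC412.t1 in an intron on V (18.9 ± 0.976; SD, n = 2).

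The piRNA genes of chromosome IV lie in clusters, and IDR peaks were more frequent there than background regions were. Clusters at IV 4800001 to 7000000, 9100001 to 9200000 and 13500001 to 17300000 held 2807, 21 and 11534 annotated piRNA genes and 69, 6 and 175 IDR peaks. Together they contained 250 of the 537 IDR peaks of the chromosome (46.6%) and 1459 of its 4725 background regions (30.9%), an odds ratio of 1.95 (p = 8.62e-13, Fisher's exact test, 2-sided). The median signal of all pooled candidate regions was slightly lower inside (25.7, 1783 regions) than outside (26.98, 3661 regions), a log2 difference of -0.07 (permutation p = 0.0138, 2-sided). That difference was not found with either replicate's list alone, at -0.01 without replicate 1 and 0.01 without replicate 2. The strongest peak of the piRNA class, at 35.6 ± 3.203 times the median IDR peak (SD, n = 2), had its summit at IV 14327183, 233 bp downstream of the 5' end of 21ur-10179 and 230 bp downstream of that of 21ur-7591. The next lay at IV 15234417 in an intron of pkd-2, 30 bp upstream of 21ur-1009 (9.40 ± 0.603; SD, n = 2).

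**Figure D4:**
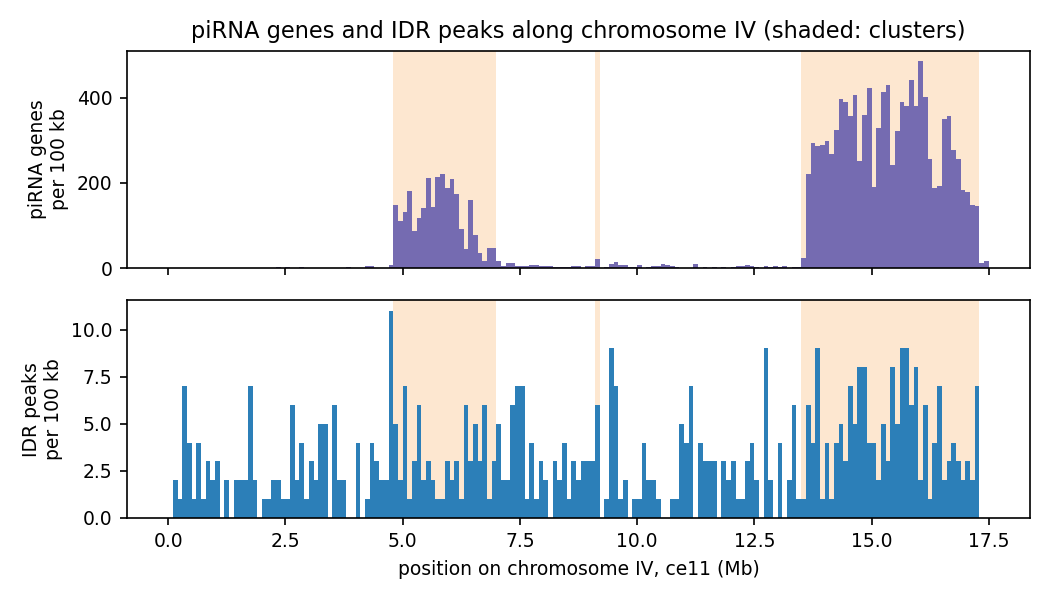
Annotated piRNA genes (upper panel) and IDR peaks (lower panel) per 100 kb along chromosome IV (position in Mb, ce11), with the 3 clusters shaded. The clusters hold 250 of the 537 IDR peaks of the chromosome.

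Chromosome X carried a larger share of the IDR peaks than of the background. It held 550 of 2926 IDR peaks (18.8%) and 3138 of 26053 background regions (12.04%), an odds ratio of 1.69 (adjusted exact p = 3.04e-22). Chromosome IV, which carries the piRNA clusters, held 18.4% and 18.1% (odds ratio 1.01, adjusted exact p = 0.781). Chromosomes I (odds ratio 0.757, adjusted p = 3.48e-07) and III (0.833, adjusted p = 0.00116) held smaller shares of peaks than of background, and chromosomes II (0.911, adjusted p = 0.128) and V (1.06, adjusted p = 0.318) did not pass Fisher's exact test (2-sided, Benjamini-Hochberg over 6 chromosomes). Per Mb, X had 31.0 IDR peaks, within the 23.5 to 32.9 of the autosomes, and the fewest background regions of any nuclear chromosome, 177 against 199 to 341. With the strongest regions of replicate 1 alone the value of III no longer passed (0.943), and V fell below 1 (0.945, not passing), and in the 1475 strongest peaks that of II passed (0.840).

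Among the 18 lists of protein-coding genes, those of the ribosome and the respiratory chain had the largest shares of genes with a peak within 500 bp of a 5' end, though not the largest odds ratios at 100 bp. An IDR summit lay within 500 bp of a 5' end at 49 of 78 ribosomal protein genes (62.8%, 95% interval 51.1 to 73.5) against 7.22% of the other genes (odds ratio 21.7, adjusted exact p = 1.11e-34). Of 31 genes of the mitochondrial respiratory chain, 16 had one (51.6%, 33.1 to 69.8; odds ratio 13.4, adjusted exact p = 7.56e-10). Translation factors (11 of 32, odds ratio 6.56, adjusted exact p = 6.69e-05), heat shock genes (8 of 24, 6.25, adjusted p = 0.00104), germline genes (6 of 20, 5.35, adjusted p = 0.00787) and genes of the piRNA and small RNA pathway (6 of 23, 4.40, adjusted p = 0.0145) were also above the other genes, and collagens, the proteins of the cuticle, were below (3 of 163, 0.232, adjusted p = 0.00787). The background matters for these calls, since peaks drawn at random from candidate regions also passed 5 of 90 adjusted list tests. Among the genes with a pooled candidate region at a 5' end, a background added after the data had been seen, ribosomal proteins (49 of 72, odds ratio 8.45, adjusted exact p = 5.97e-17) and the respiratory chain (16 of 28, 5.18, adjusted p = 0.000213) stayed above and collagens below (3 of 50, 0.244, adjusted p = 0.0459). Translation factors (odds ratio 2.36, adjusted exact p = 0.104), heat shock (3.09, adjusted p = 0.0695), germline (2.32, adjusted p = 0.300) and the small RNA pathway (2.10, adjusted p = 0.311) did not pass there. Tests were Fisher's exact tests, 2-sided, with Benjamini-Hochberg adjustment over the 18 lists.

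Members with strong peaks included rpl-15 (10.6 ± 1.16 times the median IDR peak), rpl-3 (9.73 ± 0.341) and rpl-18A (7.31 ± 0.646) among ribosomal proteins, and cox-5A (5.06 ± 0.0355) and cox-5B (2.94 ± 0.138), subunits of cytochrome c oxidase, with the ATP synthase gene atp-1 (2.37 ± 0.0851; SD, n = 2). Their summits lay 353, 277, 291, 283, 296 and 5 bp upstream of the nearest annotated 5' end. Translation factors were led by eif-3.C (3.04 ± 0.424) and heat shock genes by the neighbours hsp-16.20 and hsp-16.21, which share 1 peak (9.72 ± 1.32; SD, n = 2). The germline list was led by cpg-1, a chitin-binding eggshell protein (2.84 ± 0.126), and the small RNA list by hrde-1, a nuclear Argonaute (1.06 ± 0.0680; SD, n = 2). Without peaks within 500 bp of an RNA gene, 31 of 78 ribosomal protein genes (odds ratio 10.9) and 12 of 31 respiratory chain genes (10.3) still had a peak, and the heat shock list no longer passed (2 of 24, odds ratio 1.47, adjusted exact p = 0.778). With all peaks, 8 of the 24 heat shock genes had one, so most of those peaks lay near RNA genes. Whether the peak shared by hsp-16.20 and hsp-16.21 belongs to an RNA gene was not examined. At 100 bp from the 5' end neither ribosomal proteins (odds ratio 2.59, adjusted exact p = 0.478) nor the respiratory chain (4.46, adjusted p = 0.478) passed, and translation factors did (9.29). Over the alternatives the adjusted exact p ran from 1.96e-38 to 0.478 for ribosomal proteins, 7.56e-10 to 0.478 for the respiratory chain, 4.12e-05 to 0.104 for translation factors, 9.86e-06 to 0.778 for heat shock, 0.00333 to 0.507 for germline, 0.00497 to 0.848 for the small RNA pathway and 0.00365 to 0.478 for collagens. With the strongest regions of replicate 2 alone germline (odds ratio 3.0995) and the small RNA pathway (3.45) no longer passed, and with those of replicate 1 alone collagens (0.353) did not. In the 1475 strongest peaks the small RNA pathway (1.23) and collagens (0.335) did not pass, nor did the small RNA pathway at 1000 bp (3.11).

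The remaining lists did not pass. Peaks were found at 10 of 72 histone genes (adjusted p = 0.131), 6 of 33 spliceosome and snRNP protein genes (0.0739), 2 of 10 genes of SNAPc and piRNA transcription (0.274), 2 of 12 glycolysis genes (0.335), 1 of 6 genes of RNA polymerase III and its factors (0.477), 1 of 6 vitellogenins (0.477) and 1 of 10 neuronal genes (0.646), by Fisher's exact test with Benjamini-Hochberg adjustment. No peak was found at 31 major sperm protein genes (adjusted p = 0.274) or at the 10 marker genes each of intestine, body muscle and hypodermis (adjusted p = 1 in each exact test). The histone list passed at 1000 bp (odds ratio 2.32) and in the 1475 strongest peaks (2.94). The strongest histone peak lay between his-67 and his-68 on chromosome I (4.21 ± 1.01 times the median IDR peak; SD, n = 2). The peak of snr-4, an Sm protein gene, is that of the neighbouring U4 gene C52E4.8.

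Outside the lists and at least 500 bp from any RNA gene, the strongest protein-coding 5' end peak lay between F39H2.3 and syp-3, which encodes a synaptonemal complex protein, at I 8664524 (14.1 ± 1.76 times the median IDR peak). It was followed by the cytochrome P450 gene cyp-13A2 on II (13.4 ± 1.33), F14H8.8 on V, whose summit lies in an intron of cng-1 (11.5 ± 1.05), and T05F1.4 on I (7.94 ± 1.00; SD, n = 2). The snpc-4 gene itself (I 8962322 to 8966129), the source of the tagged protein, had 2 IDR peaks in its body or within 500 bp. The stronger had its summit at I 8962085, 237 bp upstream of the 5' end of snpc-4, with a signal of 146 and a rank of 1404 among the 2950 peaks. The replicates differed there: the signal within 250 bp of that summit was 9.99 in replicate 1 and 102 in replicate 2. In replicate 1 the strongest region of the locus had its summit at I 8966666, past the 3' end of snpc-4, with a signal of 56.9. No IDR peak lay at unc-119 (III 10902641 to 10908935), a common marker of worm transgenes that is not named in the labels. Its strongest pooled candidate region had a signal of 67.3.

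The upstream motif of piRNA genes was rarer at peak summits than beside them. The sequence CTGTTTCA, the core of the motif found upstream of many 21U-RNA (piRNA) genes, occurred on either strand within 100 bp of 24 of 2926 summits (0.820%) and in 130 of 5852 windows centred 500 bp to either side (2.22%), an odds ratio of 0.364 (p = 6.75e-07, Fisher's exact test, 2-sided). At the 73 peaks of the piRNA class it occurred in 1 summit window and in 26 of 146 flanking windows (odds ratio 0.0641, adjusted exact p = 0.00155 over the 10 classes). That class difference no longer passed with windows of 50 bp to either side (0.131), in the 1475 strongest peaks (0.120) or with the strongest regions of replicate 2 alone (0.198). The rarity over all peaks need not be specific to this motif, since base composition differs between peaks and flanks. At 2430 peaks away from structural RNA genes, 1821 sequences of the same length were less frequent at summits and 2955 more frequent. The less frequent ones included TTCTGAAA (odds ratio 0.373) and AAATTTCA (0.403). Such sequences were not tested within the piRNA class.

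Other sequences were concentrated at summits. Among the 2430 peaks away from tRNA, snRNA, SL RNA, 5S rRNA and snoRNA genes, the 8-mer with the smallest p, CGGCCGAC, occurred at 291 summits (11.98%) and in 11 of 4860 flanking windows (0.226%), an odds ratio of 60.0 (adjusted exact p = 1.67e-122). GCGGCCGA, which overlaps it by 7 bases, was at 284 summits (odds ratio 58.3, adjusted exact p = 2.54e-119), and GCGGAACC at 274 summits and in 10 flanking windows (odds ratio 61.6, adjusted p = 8.51e-116). Of 32896 8-mers tested by Fisher's exact test, 2-sided, with Benjamini-Hochberg adjustment, 2955 were more frequent at summits and 1821 less frequent. Base composition differs between peaks and flanks and 8-mers overlap, so these counts do not number separate motifs.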

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

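The test of how much of the mitochondrial genome is covered was chosen after its peaks had been seen, and the candidate-region test on ribosomal protein genes and both tests on tRNA genes were devised after the peaks of those genes had been seen but before their own values were.

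The mitochondrial genome lies outside the class and chromosome comparisons, yet it held 24 IDR peaks, with a median signal of 1689.9, against 141 for all IDR peaks, and a range of 136 to 7425. They lay in 3 regions, at positions 59 to 244, 587 to 6661 and 6723 to 13023. Broad recovery of mitochondrial DNA is a candidate explanation, since the regions covered 91.1% of the 13794 bp. Binding at mitochondrial tRNA genes was not favoured, since 4 summits lay within 100 bp of a tRNA 5' end against 4.53 for random positions (ratio 0.883, permutation p = 0.692). The control library is not analysed here, which leaves the level of mitochondrial DNA without immunoprecipitation open, and no biological explanation other than binding at tRNA genes was tested.

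Of the ribosomal protein genes, 62.8% had a peak within 500 bp of an annotated 5' end. RNA genes in or beside their promoters do not account for the whole excess, since without peaks near RNA genes the odds ratio was 10.9. Recovery at every promoter that yields a candidate region does not either, since among such genes it was 8.45. Recovery that rises with transcription or open chromatin stays open without a control library, and no other explanation was tested.

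About as many tRNA genes had no peak (296) as had one (316). Loss of reads between identical copies would leave copies with fewer peaks than unique genes, but 263 of 469 genes with an identical copy (56.1%) and 53 of 143 unique genes (37.1%) had a peak, an odds ratio of 2.17 (Fisher's exact test, 2-sided, p = 8.28e-05). Reads placed among identical copies at random could still spread peaks over them. Loss of the internal B box, a promoter element of tRNA genes, covers few of the genes without a peak, since 2.70% of them lacked its consensus. No biological explanation other than the B box was tested.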

How the results depend on the processing

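The candidate-region background and 1 summit per region were chosen after the data had been seen. Over 22 settings, 384 of 452 alternative values of 66 results kept their direction and side of the threshold or their size, 23 lost the call, 13 gained it, 13 moved and 19 reversed. The cause was not tested except where stated. Taking the strongest regions of the pooled list changed nothing by construction, since all 2950 IDR summits are among its 2950 strongest regions. Its 57 values are counted among the 384, so that count overstates stability. No direction or call changed with 1 summit per region (25 results), the ce10 lists (9), any overlap of the whole region (9) or without peaks near tRNA genes (8), though sizes did: without peaks near tRNA genes the odds ratio of SL RNA genes was 200.2 and that of other noncoding RNA genes 2.43, and with any overlap that of protein-coding 5' ends was 1.24.

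In the 1475 strongest peaks, a number fixed by construction, replicate overlap was 99.1% and 99.6% and rho 0.808, with the weaker peaks left out. There 5S rRNA genes passed as a class (19.3) and by gene (6.85), the piRNA motif difference was lost (0.120), the tRNA signal difference turned to -0.053, neurons and vitellogenins fell to an odds ratio of 0, and 0 lists lay below the other genes. Overlap of 50% of each region gave 67.7% and 73.4%, and summits within 100 bp gave 79.0% and 84.1%.

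At 100 bp, 5S rRNA genes passed (17.8), piRNA genes turned to 0.611 as a class and -0.064 in signal, microRNA signal passed (1.02), and tRNA genes on X turned to 0.949. RNA polymerase III and neurons fell to 0, with 1 list above and 0 below the other genes. At 1000 bp, piRNA genes passed as a class (1.40) and in signal (0.17), microRNA genes passed by gene (2.20), other noncoding RNA genes lost the call (1.05) and neurons turned to 0.976. Against circular shifts the observed over the mean shifted count of piRNA genes was 0.814. With mean signal, microRNA (0.84) and piRNA peaks (0.19) passed. Motif windows of 50 bp lost the piRNA difference (0.131).

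Among genes with a candidate region, 2 lists lay above the others, and RNA polymerase III (0.770), vitellogenins (0.770), glycolysis (0.963) and neurons (0.963) turned below 1. Each of these lists holds 1 or 2 genes with a peak, so few genes decide the direction. Without replicate 1 or without replicate 2, values ran from 0.165 to 0.198 for the piRNA motif, 4.46 to 44.1 for the 5S rRNA class, 0.945 to 1.05 for chromosome V, -0.055 to 0.40 for microRNA signal, -0.011 to 0.014 for candidate signal in piRNA clusters, 0 to 1.57 for intestine, 0 to 2.48 for vitellogenins and 0 to 1 for lists below the other genes.

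Lists also lost calls, 4 of them among genes with a candidate region (translation factors, heat shock, germline and the small RNA pathway) and 6 at 100 bp, all called lists but translation factors. Without replicate 1, germline (3.0995) and the small RNA pathway (3.45) lost theirs, and without replicate 2, collagens (0.353) did. In the 1475 strongest peaks the small RNA pathway (1.23) and collagens (0.335) lost theirs, as did the small RNA pathway at 1000 bp (3.11) and heat shock without peaks near RNA genes (1.47). Chromosome II gained a call in the strongest peaks (0.840), III lost its own without replicate 2 (0.943), and histones gained one in the strongest peaks (2.94) and at 1000 bp (2.32). The snRNA, SL RNA, tRNA and snoRNA classes passed under every alternative run, with odds ratios from 30.7 to 111, 51.6 to 841, 8.14 to 18.7 and 4.52 to 16.6, and against circular shifts, where the value is the observed over the mean shifted count, with 51.6, 39.7, 29.7 and 16.6. Depth is unknown, so what weaker binding a deeper library would add cannot be stated.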

Other observations

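The sequence element, the families, tRNA isotypes and pseudogenes, and the strongest peaks outside the gene classes were chosen for study after the peaks had been examined, and the tests of U6 genes, of repeats, of chromosome X without both kinds of peak, and of the element at protein-coding 5' ends and outside the gene classes were chosen after the result they address.

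The share of tRNA genes with a peak ran from 4 of 20 His genes (95% interval 5.73% to 43.7%) to 24 of 34 Ala genes (70.6%), leaving aside isotypes with fewer than 10 genes. Over the 21 named isotypes this spread did not pass (permutation p = 0.124). It passed (permutation p = 0.0427) only with 5 genes of blank isotype, none with a peak, counted as a further group. Of 209 tRNA pseudogenes, 2 had a peak (0.957%). The tandem array of 12 SL1 genes at V 17118154 to 17132107 held 1 IDR summit (250 bp at either end included), more than 250 bp from every SL1 5' end, and the span of 15 rrn-4 genes (5S rRNA) at V 17115903 to 17428996, which contains it, held 8. Of the peaks with no RNA gene within 250 bp and no protein-coding 5' end within 500 bp, the strongest had its summit in an exon of bed-2 at III 11463983, 20.7 ± 0.152 times the median IDR peak. The next lay at IV 991245, 793 bp from egrh-2 (15.8 ± 1.26; SD, n = 2).

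A 24 bp element with the consensus GCGGAACCCGCGAGATGTCGGTAC (the most frequent base at each position) was derived from the sequence upstream of 47 U1, U2, U4 and U5 genes, where it starts a median of 62 bp and ends 38 bp upstream of the 5' end. A match past a cutoff of 14.3 bits lay within 100 bp of 557 of 2926 IDR summits (19.04%) and of 286 of 26053 background regions (1.098%). The cutoff was the 99th percentile of 5000 background windows, so the low background share follows from that choice and is no separate result. The matches at IDR summits include 50 of 85 snRNA peaks, a class that holds the genes from which the element was derived. It occurred at sup-6 (II 12945004 to 12945027, minus strand, 34.9 bits), from whose family it was derived, and also at rpr-1 (I 13463885 to 13463908, 30.3 bits) and the snoRNA gene Y37E3.20 (I 2084975 to 2084998, 30.5 bits). Past the cutoff were also the strongest peak, at Y53F4B.47 (23.3 bits), mir-8196.1 on X (28.4), the tRNA gene M01E5.t1 (29.9) and the peak near 21ur-10179 (26.2), but not sls-2.4 (1.67), ZK994.7 (12.5) or C27A2.t1 (-4.90). The match at M01E5.t1 lies on the strand opposite to the tRNA gene, so it need not belong to that gene.

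The element may place SNPC-4 at genes beyond the snRNAs. Compared with windows beside the same peaks, it was enriched at snoRNA peaks (36 of 105, odds ratio 54.3) and at SL RNA peaks (13 of 21, odds ratio 135 with 0.5 added to each count), neither of which entered the element or the 8-mer counts of the report. It was also more frequent at the peaks of piRNA genes (34 of 73, odds ratio 126), at protein-coding 5' ends (68 of 1024, odds ratio 24.2) and at peaks outside the gene classes (326 of 1063, odds ratio 85.0). The 8-mer GCGGAACC, with which the element begins, had already been found at 274 of 2430 summits that include these, so those 3 values restate that count and decide nothing. At tRNA peaks it was rare (7 of 283, odds ratio 3.56), and whether it plays a part there cannot be told apart from chance at 7 peaks (adjusted p = 0.0543 by Fisher's exact test). Most protein-coding peaks lacked it. Of 2537 matches past the cutoff in the nuclear genome 573 had an IDR peak (22.6%). Over bins of score the share was 10.1% at 16 to 18 bits and 51.6% at 24 bits and above.

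The U6 genes, which did not enter the element, differed in their match to it. The best upstream score had a median of 13.4 bits at 11 genes with a peak and -7.52 bits at 11 without, a difference of 20.96 bits (exact permutation p = 0.00286, 2-sided). The split is not clean: 4 of the 11 genes with a peak passed the cutoff of 14.3 bits, and 1 of the 11 without did, Y17G9A.90 at 19.9 bits. A candidate explanation is that U6 genes without a peak have a weaker binding site, though several lie side by side with identical scores and are not independent.

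Peaks with the element outside the gene classes held more repeated sequence than those without it. A median of 17.5% of their 16-mers (quartiles 7.66% and 35.3%) occurred at least 10 times in the genome, against 2.15% at peaks without it, a difference of 15.3 (p = 1e-04, the smallest the permutations can give). Those windows include the element itself, so its own 16-mers may make up part of the difference. Whether SNPC-4 may sit at the element or reads collect at repeats cannot be told apart, since a repeat that holds the element brings both and the difference is short of the margin set for the test.

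The excess of IDR peaks on X was lower without peaks at tRNA genes (odds ratio 1.42) and without peaks with the element (1.47), and neither alone decides. Without both it was 1.11 (p = 0.122, Fisher's exact test), with 271 of the 550 peaks on X left. This does not decide the source of the excess. X held more peaks at tRNA genes (126) and with the element (155) than any other chromosome, so leaving them out lowers its odds ratio by itself. Per Mb, X had 31.0 IDR peaks, within the 23.5 to 32.9 of the autosomes. It had the fewest background regions of any nuclear chromosome (177 per Mb), which raises the odds ratio too. In the piRNA clusters of chromosome IV the odds ratio without peaks with the element was 1.57 (168 of 415 peaks inside against 1406 of 4652 background regions), so an excess remained there. Whether the element brings about any part of it was not tested. With 1 group, the design offers no further biological explanation to test.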
